A study of Homo sapiens with 121 samples.

How the data were processed

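DNA methylation of CLL cells from human donors was measured by bisulfite sequencing. Per the labels' protocols, genomic DNA was cut with the enzyme MspI, joined to barcoded adapters, converted with bisulfite in 2 rounds with a kit, amplified by PCR and sequenced, and whole-genome bisulfite sequencing (WGBS) is named as a further method. Reads were aligned to hg19 with BSMAP, per the submitters' processing notes, whose version is not given in the sources used here. The deposited values are read counts at each CpG, per the file headers: methylated and unmethylated reads, and the same reads split into concordantly methylated, concordantly unmethylated and discordant reads. No normalization of the counts is recorded by the authors, per the labels. Whether duplicate reads were removed is not given in the sources used here.

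The values were checked before use. All of 884174 CpG positions listed by any first library are CG in the GRCh37 sequence, which has the coordinates of hg19 for the autosomes. Methylated plus unmethylated reads equalled concordant plus discordant reads with 0 mismatches, the smallest number of reads at a listed CpG and strand was 11, and only autosomes and mitochondrial DNA were listed. Counts of both strands of a CpG were added where both were listed. Groups and pairs were taken from the labels: donors sampled at a single time, time point 1 and time point 2. The name of 1 file gives a time point where its label gives none, and the label was followed. For 2 samples there is a second library, whose file name contains WGBS and whose label does not state the kind. These second libraries were left out of all comparisons of groups. Donors with both time points entered the cross-section once, with time point 1.

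The pairs come from the labels, in which both time points carry the same donor, so the donor was used as a block. As a check for mixed-up samples, the correlation across CpGs was computed for all pairs of libraries. The median was 0.951 for the 14 same-donor pairs and 0.902 for 6998 pairs of different donors. Of 13 second time points, 11 were closest to their own first time point, and no 2 libraries shared more than 66.5% of their values. The ranges overlapped, with a lowest r of 0.908 for the same donor and a highest of 0.971 for different donors. For 1 donor the second time point was nearer to another donor's first time point than to its own, by 6.35 against 6.51 points per CpG. Its correlation was still higher with its own, 0.955 against 0.914. For 1 other donor it was both nearer to and better correlated with another donor's first time point. The differences were 5.89 and 7.07 points per CpG and the correlations 0.956 and 0.942, so a mixed-up sample is not excluded. The likeness of these donors ran both ways. The second time point of the donor thus matched had r = 0.971 with its own first time point. It had r = 0.945 with the first time point of the donor in question, and at most 0.921 with those of further donors. Both were counted as separate donors.

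A library needed 10000 CpGs, which left 88 single-time and 13 first time point libraries (3 and 1 were below), and a pair needed 5000 shared CpGs of at least 10 reads. For each library the mean methylation of CpGs was computed, with the shares under 20%, from 20 to 80% and over 80%, the mean absolute difference of neighbouring CpGs at most 50 bp apart, and the discordant share of reads. Genes were taken from GENCODE release 44, lifted to GRCh37. A promoter was 1000 bp either side of the transcription start with the most calls of a gene, and was called CpG-dense from an observed to expected CpG ratio of 0.6. Other CpGs were gene body or intergenic by protein-coding genes. A region's methylation is the sum of methylated calls over all calls, so a read counts once at each of its CpGs. A promoter needed 20 calls in a donor and 50 donors, or 20 calls in both libraries of 10 pairs, as did windows of 1000 bp.

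Group differences were tested with permutation tests of 100000 resamples, pairs with exact sign flips, and single-donor changes with Fisher's exact test at a difference of 20 percentage points. Donor spread was tested against read sampling with a chi-square overdispersion test. Regions over time were tested with a quasi-binomial logistic model with a donor block, 0.5 added to both counts and a dispersion of at least 1, and with limma on the paired differences as the alternative. All families were adjusted by the Benjamini-Hochberg method at 0.05. Planned tests were adjusted over the planned family, and added ones over planned and added tests together. Wilson intervals are at 95%. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.

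The tests, thresholds, gene lists and the rule for named genes were chosen before the data were examined, except where the text says that a measure was added. The discordant share in every use, the comparison at the same CpGs as the 50 deeper libraries, the SD at matched CpGs, the comparisons without libraries in which over 2% of rows were merged from both strands, or without their pairs (where a region then needed 6 pairs), the test of imprinted promoters, the changes within contexts and the mitochondrial calls were added after the data were seen. The comparison at the same CpGs takes each library's mean deviation from the 50 libraries with the most CpGs, at CpGs listed in at least 20 of these, and adds it to their mean. The rule named the 10 promoters with the largest SD past the overdispersion test, the 10 highest means and 5 smallest SDs in the gene lists, and of each list members with the largest SD or change. For change over time it named the 5 regions with the smallest p in each direction, because fewer than 5 passed. The 16 gene lists hold genes often studied in CLL, CLL driver genes, CLL surface markers, B lineage, T and NK cell and myeloid genes, HOX genes, developmental transcription factors, WNT inhibitors, tumour suppressors, imprinted genes, germline and cancer-testis genes, protocadherins, methylation enzymes, apoptosis genes and housekeeping genes. Of 609 list entries 597 were matched to an autosomal gene. Genes in several lists count in each. The value of 1 list member that the rule named is not reported here. Lists were compared with 10000 random lists of the same size, drawn within 20 bins of mean methylation that held equal numbers of promoters.

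The models were tested on simulated data. With binomial counts and no donor spread, the overdispersion test called 311 of 11805 promoters and gave 9.67% of them an unadjusted p under 0.05, so it calls too often. It found 185 of 200 promoters with an SD of 10 points. The region model, with the spread fitted to each promoter, recovered 86 of 100 promoters changed by 10 points and 97 of 100 changed by 20 points. It called 27 of 6315 unchanged promoters, 12.9% of all its calls, which is more than the adjusted threshold of 0.05 allows for. A first simulation gave all promoters the same spread and was replaced after its outcome was seen: it recovered 82 and 100 promoters, and called 109 of 6315 unchanged ones, 37.5% of all its calls. Pairs simulated without change, with counting error only, gave 0 calls by Fisher's exact test.

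The alternatives were 20 reads per CpG, each CpG thinned to 10 reads, a panel of 235841 CpGs listed in the libraries of at least 0.5 of the donors, 100000 CpGs per library, 50000 shared CpGs per pair, 10 to 90% as intermediate, 10 or 50 calls per region, promoters of 500 bp either side, 30 points for Fisher's exact test, limma, no donor block, and each pair left out in turn. Depth limits the values as follows: the median reads per CpG lay between 12 and 43 in each library, so a single CpG has a coarse level, and levels are therefore given over many CpGs. X and Y chromosomes are absent from the files. Expression, genotypes and clinical data were not used here.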

Results

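DNA methylation was measured by bisulfite sequencing of genomic DNA from chronic lymphocytic leukemia (CLL) cells, the clonal mature B cells of this leukemia, with the methylation disorder of these cells as the subject named by the series title. The main data set was made of libraries of reduced representation bisulfite sequencing (RRBS), in which the enzyme MspI cuts at CCGG sites so that CpG-dense fragments are enriched. It comprised 91 libraries of donors sampled at a single time and 14 libraries each of a first and a second time point from the same 14 donors. In addition, 1 donor sampled at a single time and 1 first time point had a second library. The single-time libraries listed between 3781 and 627284 CpGs (median 258997). The first time point libraries listed between 7776 and 515144 (median 278516) and the second time point libraries between 11990 and 687192 (median 355668). The median number of reads per listed CpG ranged from 12 to 42 in the single-time libraries (median 15). It ranged from 13 to 21 in the first time point libraries (median 15) and from 12 to 43 in the second time point libraries (median 16). CpG calls per library, in which a read counts once for each of its CpGs, ranged from 68052 to 28057633, from 266402 to 11674027 and from 230212 to 29617651 in the same order. Intervals and floors given here cover counting error only, because reads without molecular identifiers are not independent molecules.

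The cross-sectional part asked how CLL methylomes are built and how much they differ between donors. Over 101 donors with at least 10000 CpGs, most CpGs of these CpG-dense fragments were unmethylated. A share of 61.8% ± 6.89 of CpGs (SD, n = 101) had a methylation level under 20%, 19.4% ± 4.23 lay between 20 and 80% (intermediate), and 18.8% ± 3.02 lay above 80%. The mean CpG methylation was 29.3% ± 5.31. Neighbouring CpGs at most 50 bp apart differed by 7.44 ± 1.04 percentage points. Discordant reads, those that carry both methylated and unmethylated CpGs, made up 22.2% ± 3.97 of reads at a CpG. At CpGs of intermediate methylation the discordant share was 55.5% ± 2.63, against 8.03% ± 0.978 at unmethylated and 34.0% ± 3.39 at methylated CpGs. These are descriptions with no test.

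The level of a library went with the number of CpGs it listed. Pearson's r of CpG number with mean methylation was 0.773 and Spearman's rho 0.786 (n = 101, both permutation p = 1e-05, the smallest that the permutations can give; adjusted p = 1e-05). The r was 0.771 without the 2 farthest libraries, chosen by CpG number. It was 0.761 among the 51 libraries with fewer CpGs and 0.106 (p = 0.469) among the 50 with more. The latter include 3 first time points of low mean methylation, 20.001 to 25.7%, against 28.9% or more in the others. The r without these 3 was not computed, so whether the relation holds among the libraries with more CpGs stays open. The discordant share followed the CpG number with r = 0.779 and rho = 0.787 (both p = 1e-05), with r = 0.770 without the 2 farthest libraries and 0.747 and 0.0813 in the libraries with fewer and with more CpGs. The intermediate share followed it with r = 0.736 and rho = 0.737 (both p = 1e-05), with r = 0.736 without the 2 farthest and 0.725 and 0.0180 in these groups of libraries. At CpGs with at least 20 reads the r was 0.271 with mean methylation (adjusted p = 0.0074), 0.652 with the discordant share (1.3e-05) and 0.192 with the intermediate share (0.0549). Each library was then set against the mean of the 50 deeper libraries at the very CpGs it listed. The r with mean methylation was then 0.0861 (p = 0.392, adjusted p = 0.470) and that with the discordant share 0.0432 (p = 0.668), while the intermediate share kept r = 0.287 (p = 0.0037, adjusted p = 0.0056). Within the libraries with fewer and with more CpGs the latter r was 0.0213 (p = 0.880) and 0.0977 (p = 0.503). The levels over the 101 donors narrowed to 33.0% ± 1.17 for mean methylation, 21.9% ± 1.53 for the intermediate share and 25.1% ± 1.34 for the discordant share. These 3 relations were added after the data were seen and adjusted with the 5 relations given further on, 8 in all, by the Benjamini-Hochberg method. At the same CpGs, where the neighbour difference was not computed, the adjustment was over 6 relations.

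**Figure D1:**
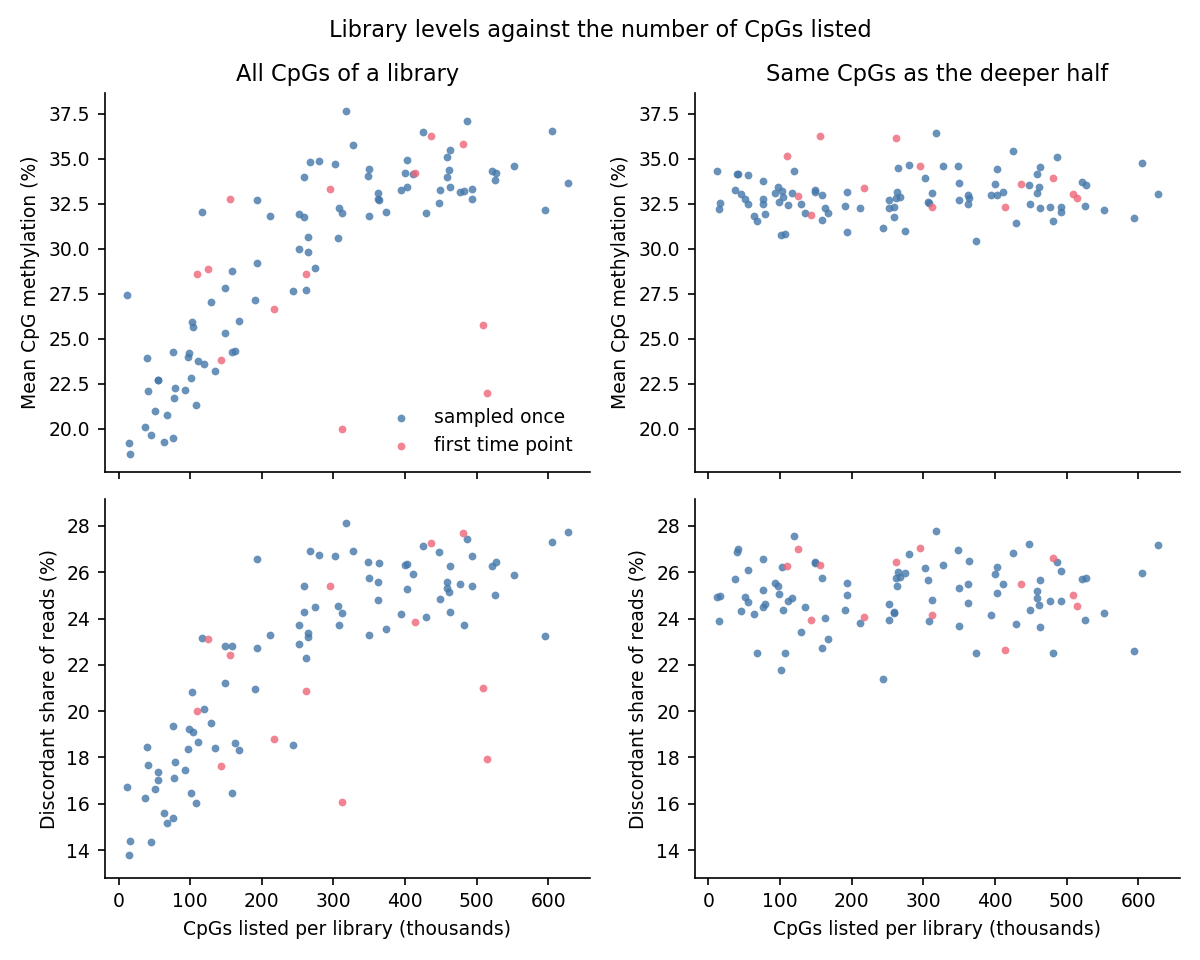
Mean CpG methylation in percent (top) and discordant share of reads in percent (bottom) of 101 donors, 1 point per library, against the number of CpGs listed in units of 1000, for donors sampled at a single time (blue) and first time points (red). With all CpGs of a library (left) the levels rose with the CpG number (r = 0.773 and 0.779), and at the same CpGs as the 50 deeper libraries (right) r was 0.0861 and 0.0432.

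Whether the donors followed over time started from the levels of the donors sampled at a single time was tested next, and no difference was detected over all listed CpGs. Mean methylation was 29.3% ± 5.34 in 88 single-time donors and 29.0% ± 5.26 in 13 first time points, a difference of -0.334 percentage points (two-sided permutation test, p = 0.836, adjusted p = 0.878 over 3 measures). The intermediate share was 19.6% ± 4.23 against 18.2% ± 4.18 (difference -1.35, p = 0.283, adjusted p = 0.849). The neighbour difference was 7.43 ± 1.04 against 7.48 ± 1.11 points (difference 0.0485, p and adjusted p = 0.878). The discordant share was 22.3% ± 4.03 against 21.7% ± 3.68 (difference -0.630, p = 0.60, adjusted p = 0.878 over 4 measures). The difference turned with depth. Among the 51 libraries with fewer CpGs the mean was 25.1% ± 4.13 (n = 45) against 28.2% ± 2.94 (n = 6), permutation adjusted p = 0.158. Among the 50 with more CpGs it was 33.7% ± 1.73 (n = 43) against 29.6% ± 6.86 (n = 7), permutation adjusted p = 0.0066. The intermediate and discordant shares of the latter differed by -3.57 and -2.84 points (permutation adjusted p = 0.0066 and 0.0059), and with at least 100000 CpGs per library (69 against 13 donors) by -2.91 and -2.16 (adjusted p = 0.0221 and 0.0482). The difference among the libraries with more CpGs rested on 3 of the 7 first time points, with means from 20.001 to 25.7% against 33.3 to 36.3% in the other 4 and intermediate shares from 11.99 to 16.3% against 20.2 to 24.5%. These 3 stood apart from all other libraries of the cross-section in the rows of both strands that were merged, 2.73 to 7.15% of their rows against at most 1.53%. Without them, an alternative added after the data were seen, the differences among the libraries with more CpGs were 1.22 points in mean methylation (43 against 4 donors, permutation adjusted p = 0.266), 0.368 in the intermediate share (0.677) and 0.476 in the discordant share (0.677). At the same CpGs as the deeper libraries, an alternative added after the data were seen, the first time points were higher by 0.807 points (33.7% ± 1.44 against 32.9% ± 1.10, p = 0.0198, adjusted p = 0.0396 over 2 planned measures). The difference was 1.65 points among the libraries with fewer CpGs (permutation adjusted p = 0.0028) and 0.0292 among those with more (permutation adjusted p = 0.952).

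Promoters of these cells were largely unmethylated. The listed CpGs of gene bodies and intergenic DNA had higher mean levels, although most of them were not intermediate. Promoter CpGs, within 1000 bp of a transcription start, had a mean methylation of 6.65% ± 1.48 (n = 101), gene body CpGs 55.3% ± 6.32 and intergenic CpGs 52.5% ± 4.90. CpG-dense promoters (observed to expected CpG ratio of at least 0.6) lay at 5.63% ± 1.31 and CpG-poor promoters at 15.2% ± 3.27, lower in the dense kind in 101 of 101 donors. Intermediate CpGs made up 7.25% ± 1.62 of dense promoters, 11.4% ± 2.26 of poor promoters, 29.3% ± 6.02 of gene bodies and 34.6% ± 5.15 of intergenic CpGs. Discordant reads followed the same order, with 9.91% ± 1.77, 14.3% ± 2.30, 33.7% ± 4.87 and 36.4% ± 4.803. At intermediate CpGs alone this order was not seen. There the discordant share was 55.3% ± 3.15, 53.6% ± 2.77, 56.6% ± 2.18 and 54.8% ± 3.52, which was not tested. Neighbouring CpGs differed by 3.56 ± 0.603, 5.25 ± 0.748, 11.4 ± 1.12 and 11.9 ± 1.14 points in the same contexts.

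All 9 planned differences between contexts, and the 3 added for the discordant share, had p and adjusted p = 1e-05 in a two-sided sign-flip permutation test over donors. This is the smallest p that 100000 permutations can give. Promoters lay below gene bodies by a mean methylation difference of -48.6 ± 5.22 points, by an intermediate share difference of -21.6 ± 5.01 and by a discordant share difference of -23.3 ± 3.83, in 101 of 101 donors each. Gene bodies lay above intergenic DNA in mean methylation by 2.73 ± 2.58 points in 94 of 101 donors. They lay below it in the intermediate share by -5.25 ± 1.77 and in the discordant share by -2.77 ± 0.837, both in 101 of 101 donors. The higher mean methylation of gene bodies turned to -2.58 ± 7.90 points (adjusted p = 0.0011) at CpGs with at least 20 reads, although gene bodies were still higher in 58 of 101 donors.

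Across donors, higher mean methylation went with more intermediate CpGs and with more local disorder. Mean methylation and the intermediate share had r = 0.940 and rho = 0.904, and mean methylation and the neighbour difference r = 0.927 and rho = 0.903. The intermediate share and the neighbour difference had r = 0.915 and rho = 0.896 (n = 101, all 3 relations with permutation p and adjusted p = 1e-05, the smallest possible). Without the 2 farthest libraries r was 0.939, 0.921 and 0.910. The discordant share had r = 0.962 and rho = 0.946 with mean methylation and r = 0.973 and rho = 0.959 with the intermediate share (both p = 1e-05, adjusted p over 8 relations 1e-05). Without the 2 farthest libraries these r were 0.959 and 0.972. Within the libraries with fewer and with more CpGs, r was 0.897 and 0.853 for mean methylation and intermediate share and 0.905 and 0.808 for mean methylation and neighbour difference. It was 0.854 and 0.834 for intermediate share and neighbour difference, 0.922 and 0.915 for mean methylation and discordant share, and 0.956 and 0.934 for intermediate share and discordant share. In the libraries with more CpGs these relations leaned on a few libraries. There rho was 0.618, 0.646, 0.690, 0.781 and 0.811 in the order given, and r without the 2 farthest libraries was 0.667, 0.577, 0.657, 0.794 and 0.856. At the same CpGs as the deeper libraries mean methylation had r = 0.515 with the intermediate share and r = 0.749 with the discordant share (both p = 1e-05).

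Between donors, promoters ranged from fixed to switching between unmethylated and methylated. Of 12005 promoters with at least 20 CpG calls in at least 50 donors, 10606 had a mean methylation under 20%, 1206 between 20 and 80% and 193 above 80%. The promoter of GRAMD4 (ENSG00000075240, hg19 chromosome 22, 47069505 to 47071505), which encodes a protein linked to cell death, had the largest spread, 61.4% ± 36.8 (n = 57), under 20% in 12 donors and above 80% in 27. Only 5 CpGs of this region were listed in many donors, so the value need not hold for the whole promoter. CDKL4 (chromosome 2, 39470056 to 39472056), a cyclin-dependent kinase-like gene, had 49.8% ± 33.7 (n = 67), under 20% in 18 donors and above 80% in 20. LATS1, a kinase of the Hippo pathway, had 24.4% ± 32.8 (n = 57) and STX8, a syntaxin of endosomes, 37.4% ± 32.8 (n = 82). PRR33 (chromosome 11, 1912125 to 1914125) had 44.3% ± 31.1 (n = 81) and TNNI2, fast skeletal troponin I, 40.3% ± 30.9 (n = 51). EMC9, a subunit of the membrane protein complex of the endoplasmic reticulum, had 30.5% ± 30.7 (n = 58), and PMM1, a phosphomannomutase, 42.3% ± 30.6 (n = 62). FAAP20, of the Fanconi anemia core complex, had 61.01% ± 30.6 (n = 77), and RRP12, needed for ribosome maturation, 47.9% ± 30.4 (n = 54). The RRP12 region is shared with the divergent glycolysis gene PGAM1, so the value cannot be split between them.

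Part of this spread came with the CpGs that each library listed. With each CpG set against its mean over donors, and CpGs of fewer than 20 donors left out, the SD was 36.8 for GRAMD4, 35.2 for CDKL4 and 31.1 for PRR33. It was 6.02 for LATS1, 2.47 for STX8, 4.79 for TNNI2, 3.27 for EMC9, 4.16 for PMM1, 8.67 for FAAP20 and 11.9 for RRP12. By this matched SD, added after the data were seen, the 10 most spread promoters began with GRAMD4, CDKL4 and PRR33. They included SLC17A3 (50.2% ± 29.5, matched SD 29.5, n = 80), a phosphate and urate transporter, and BCL9L (27.6% ± 29.5, matched SD 29.5, n = 77), a coactivator of beta-catenin. They also included DLEU7 (39.6% ± 29.2, matched SD 29.1, n = 56), at chromosome 13 51416828 to 51418828, which lies in the 13q14 region often deleted in CLL. The others were CLEC20A (30.1% ± 28.9, matched SD 28.7, n = 77), a lectin gene, and CNKSR1 (63.6% ± 28.4, matched SD 28.4, n = 53), a scaffold of Ras signalling. The last were HOXA4 (54.9% ± 26.9, matched SD 28.02, n = 69) and SSH3 (30.4% ± 28.05, matched SD 27.4, n = 60), a cofilin phosphatase. The CpGs listed in many donors were 5 each at GRAMD4, PRR33 and CLEC20A and 4 each at SLC17A3 and CNKSR1. The other promoters had from 9 at CDKL4 to 18 at DLEU7. With promoters of 500 bp either side GRAMD4 and PRR33 were not measured in enough donors. Where CpGs were few, the SD need not describe the whole promoter. Matched SDs of 10 points or more were found at 430 of 2167 CpG-poor promoters (19.8%) and at 1121 of 9838 CpG-dense promoters (11.4%), a difference that was not tested.

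The spread exceeded read sampling at 3786 of the 12005 promoters (chi-square overdispersion test, one-sided, Benjamini-Hochberg adjusted over all 12005), among them the 17 promoters named so far. At these depths the test called 311 of 11805 promoters simulated without donor spread, so a call alone is weak evidence for a promoter of small SD. The test used all listed CpGs, and the simulation held no differences in level from libraries that list different CpGs. A call at a large SD therefore need not mean donor spread at the same CpGs. Of the 10 promoters named for the largest SD, 7 had a far smaller SD at matched CpGs and 3 did not. In the fixed gene lists the smallest SDs were those of PPIA, a cyclophilin (0.0879% ± 0.174, n = 97), and CDKN1B, the cell cycle inhibitor p27 (0.0504% ± 0.177, n = 73). They were followed by RB1, the retinoblastoma gene (0.0964% ± 0.194, n = 83), REEP5 (0.126% ± 0.205, n = 95) and H1-4, a linker histone (0.0912% ± 0.229, n = 96). The highest means in the lists were those of germline genes, with DAZL at 98.2% ± 2.45 (n = 63), TDRD6 at 96.6% ± 4.38 (n = 63) and SPATA22 at 95.9% ± 3.76 (n = 60). The germline genes TDRD12 at 95.6% ± 8.14 (n = 87), ASZ1 at 93.8% ± 8.28 (n = 68), RNF17 at 93.4% ± 5.66 (n = 88) and PIWIL1 at 92.3% ± 9.73 (n = 63) came next. They were followed by HOXB3 at 92.3% ± 10.1 (n = 66), EZH1, a Polycomb methyltransferase, at 91.98% ± 16.03 (n = 58, matched SD 3.19) and the imprinted gene MKRN3 at 89.0% ± 20.3 (n = 80). The HOXB3 and EZH1 values are those of the transcription start with the most calls, which need not be the start used in these cells.

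Gene groups differed in how their promoters were methylated. Germline and cancer-testis genes were methylated, with 10 of 16 measured promoters above 80%, 3 between and 3 under 20% (list mean 68.8%). Their largest SDs were at MOV10L1 (70.5% ± 19.2, n = 87), an RNA helicase of the piRNA pathway, and BOLL (20.3% ± 15.01, n = 88). Protocadherins, adhesion genes clustered on chromosome 5, were intermediate at 19 of 21 measured promoters (list mean 49.5%). They were led in SD by PCDHGC4 (43.5% ± 24.6, n = 83) and PCDHGA1 (57.02% ± 24.4, n = 69), whose matched SDs were 12.9 and 24.4. HOX genes split into 12 promoters under 20%, 19 between and 2 above 80% (list mean 28.5%), with HOXA6 at 33.3% ± 19.7 (n = 85) and HOXD10 at 44.7% ± 19.1 (n = 69). Developmental transcription factors, bound by Polycomb in embryonic stem cells, were under 20% at 47 of 95 promoters and intermediate at 48 (list mean 21.5%), with IRX2 at 46.7% ± 20.7 (n = 80) and OLIG3 at 45.8% ± 19.97 (n = 65). Imprinted genes were under 20% at 14 of 26, intermediate at 11 and above 80% at 1 (list mean 25.5%), with NNAT at 70.4% ± 23.4 (n = 86) and NDN at 49.98% ± 19.4 (n = 71). Genes whose methylation is often studied in CLL were under 20% at 9 of 14 and intermediate at 5 (list mean 19.2%), with ID4 at 52.4% ± 17.4 (n = 92), SPART at 16.8% ± 17.03 (n = 61) and TCL1A at 5.63% ± 7.57 (n = 85). Inhibitors of WNT signalling were under 20% at 16 of 20 and intermediate at 4 (list mean 9.30%), with DACT2 at 26.98% ± 14.9 (n = 85), SFRP1 at 23.8% ± 14.5 (n = 77) and DKK1 at 22.8% ± 13.7 (n = 80).

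The other lists had mostly unmethylated promoters among those measured. Of some lists only a part was measured, 9 of 46 T and NK cell genes, 8 of 40 myeloid, 16 of 45 B lineage and 5 of 13 surface marker genes. The same holds for lists given above, with 21 of 53 protocadherins and 16 of 28 germline and cancer-testis genes measured. The counts of all these lists describe the measured promoters and not the whole lists. The genes recurrently mutated in CLL were under 20% at 19 of 19 promoters (list mean 0.215%), with NOTCH1 at 0.747% ± 1.14 (n = 94), CHD2, a chromatin remodeller, at 0.213% ± 0.685 (n = 70) and MGA, a partner of MAX, at 0.491% ± 0.684 (n = 96). CLL surface markers were under 20% at 5 of 5 (list mean 1.75%), with ITGA4 at 5.02% ± 4.99 (n = 89), CD38 at 2.47% ± 3.27 (n = 97) and ROR1 at 0.524% ± 1.19 (n = 89). B lineage genes were under 20% at 15 of 16 (list mean 5.15%), the exception being CD40 at 71.9% ± 5.24 (n = 55). Apoptosis genes were under 20% at 21 of 22 (list mean 3.24%), the exception being BCL2A1 at 65.6% ± 7.55 (n = 60), with BIRC5 at 1.16% ± 1.90 (n = 82) and MCL1 at 0.267% ± 1.26 (n = 99). At a minimum of 50 calls per donor, which CD40 and BCL2A1 did not reach in enough donors, the B lineage mean was 0.716% and the apoptosis mean 0.272%. With promoters of 500 bp either side CD40 and BCL2A1 were not measured in enough donors either. Then 12 of 12 B lineage and 20 of 20 apoptosis promoters were under 20%. The CD40 and BCL2A1 values are those of the start with the most calls, which need not be the start used in these cells. Methylation and Polycomb enzymes were under 20% at 20 of 21 (list mean 5.33%), with EZH2 at 9.70% ± 8.29 (n = 98) and TET1 at 2.50% ± 5.44 (n = 63). Housekeeping genes were under 20% at 32 of 36 (list mean 5.99%), with UBB at 41.2% ± 17.4 (n = 76) and RPLP0 at 43.7% ± 14.7 (n = 78, matched SDs 3.84 and 4.50), and tumour suppressors were at 30 of 32 (list mean 4.51%), with DAPK2, a death-associated kinase, at 13.1% ± 19.7 (n = 55), CDH13 at 21.5% ± 15.02 (n = 90), BRCA1 at 9.59% ± 14.2 (n = 69) and CDH1 at 18.9% ± 13.97 (n = 82). Markers of the other blood cells that such a sample could hold were under 20% at 9 of 9 T and NK cell promoters (list mean 8.66%), with GATA3 at 17.8% ± 14.2 (n = 75), BCL11B at 15.6% ± 11.03 (n = 92) and CD8A at 12.7% ± 10.3 (n = 98). They were under 20% at 7 of 8 myeloid promoters (list mean 12.2%), with ELANE, the neutrophil elastase, at 70.6% ± 18.7 (n = 74). With promoters of 500 bp either side some of the named means were far lower, at 0.367% for STX8, 0.125% for EMC9, 3.85% for PCDHGC4, 0.635% for UBB, 0.420% for EZH2 and 2.29% for CD8A. Those of HOXD10 and BCL11B were higher at 60.2% and 27.8%, and 8 of 9 T and NK cell promoters were then under 20%.

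Against promoters from the same bins of mean methylation, the reads of some groups were more disordered. The 20 bins held equal numbers of promoters, and 10606 of the 12005 promoters had a mean under 20%. Promoters of higher methylation therefore shared few, wide bins. Differences in level within a bin can add to these contrasts, and this was not tested. The median discordant share of developmental transcription factors was 42.6%, against 34.1% in 10000 random lists of the same size from these bins (adjusted p = 0.0032). That of HOX genes was 46.4% against 35.02% (adjusted p = 0.0112). That of protocadherins was 54.7% against 44.5% (adjusted p = 0.0397) and that of WNT inhibitors 21.7% against 13.0% (adjusted p = 0.0384). Imprinted promoters had fewer discordant reads, 13.0% against 22.04% (adjusted p = 0.0397), and germline promoters 20.3% against 37.2% (p = 0.0260, adjusted p = 0.0693). For the other 10 lists the adjusted p was 0.175 or higher. These tests were two-sided, were added after the data were seen and were adjusted over the 16 lists. With 50 calls per donor only developmental transcription factors (adjusted p = 0.0032) and HOX genes (0.0224) stayed past 0.05, and with promoters of 500 bp either side only developmental transcription factors did (0.0288).

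**Figure D2:**
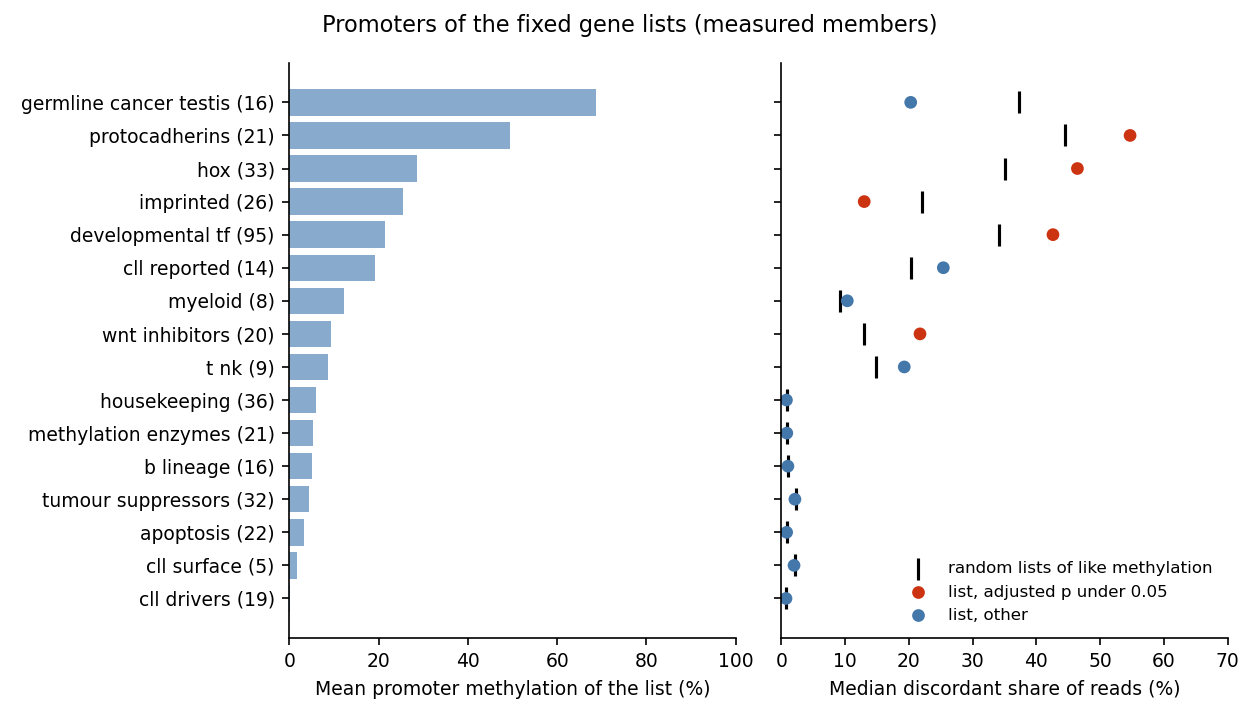
Left, bars of the mean promoter methylation in percent of the 16 gene lists, with the number of measured promoters in brackets. Right, points of the median discordant share of reads in percent of each list (red for adjusted p under 0.05). Black marks give the median of 10000 random lists from the same bins of mean methylation, which are wide at high methylation. Imprinted promoters lay at 13.0% against 22.04% and protocadherins at 54.7% against 44.5%.

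The planned test of donor spread set the median SD of each list against random lists from the same bins of mean methylation (two-sided), and 0 of the 16 lists passed. The wide upper bins limit this test and the one at matched CpGs in the same way. The smallest adjusted p was 0.125, for developmental transcription factors, whose median SD was 12.8 against 14.03 points. At matched CpGs this list lay on the other side, 12.3 against 11.1 points (p = 0.0350, adjusted p = 0.112), and with 50 calls per donor it passed there (12.27 against 10.5, adjusted p = 0.0176). An unadjusted p under 0.05 was found for these and for 1 other list, the genes often studied in CLL (13.2 against 9.73, p = 0.0386). With the SD at matched CpGs, added later, the median SD was higher than in random lists for imprinted genes (11.7 against 6.44 points, adjusted p = 0.0128), protocadherins (16.4 against 9.42, adjusted p = 0.0128), genes often studied in CLL (11.8 against 6.50, adjusted p = 0.0245) and HOX genes (13.4 against 9.94, adjusted p = 0.0248). With 50 calls per donor the adjusted p of these 4 was 0.0160, 0.122, 0.0320 and 0.122, and with promoters of 500 bp either side it was 0.0587, 0.355, 0.0587 and 0.0587.

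At imprinted promoters, where the copies from the mother and the father differ, intermediate methylation was carried mostly by concordant reads. In each of 63 donors with at least 50 imprinted promoter CpGs of intermediate methylation, the discordant share at these CpGs was lower than at intermediate CpGs of other promoters, 26.97% ± 6.73 against 56.03% ± 2.73, a difference of -29.1 ± 6.63 points (two-sided sign-flip permutation test, p = 1e-05, the smallest the permutations can give). MEST, a paternally expressed gene, gave 15.6% of the imprinted values, GNAS-AS1 10.4%, KCNQ1OT1, the RNA of the KCNQ1 domain, 8.44% and IGF2, a growth factor gene, 6.88%. This single test was added after the data were seen.

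**Figure D3:**
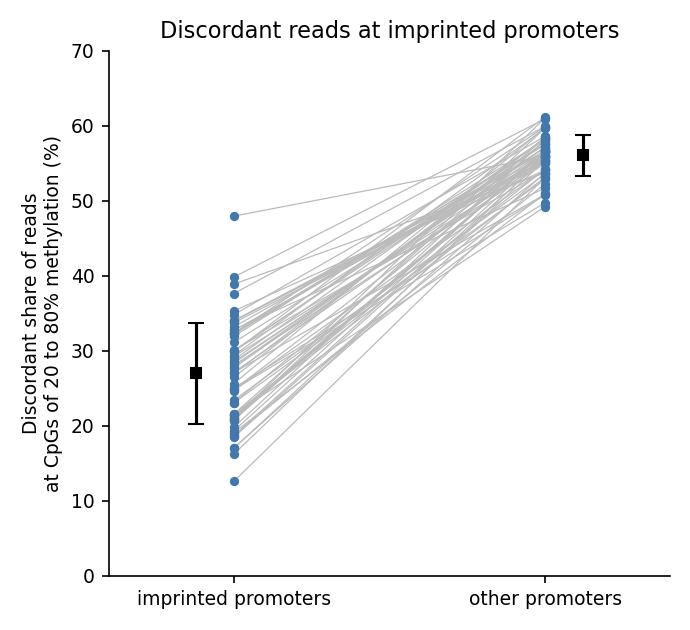
Discordant share of reads in percent at CpGs of 20 to 80% methylation in imprinted and in other promoters of 63 donors, with a grey line for each donor and black squares with bars for the mean ± SD. Imprinted promoters were lower in 63 of 63 donors (26.97% ± 6.73 against 56.03% ± 2.73).

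The longitudinal part asked what changes within a donor between time points. Over the CpGs shared by both libraries of a donor, the global levels did not differ detectably. Of the 14 pairs, 1 shared 4896 CpGs, fewer than the 5000 required, and was left out. Mean methylation was 27.8% ± 6.68 at the first and 28.05% ± 6.50 at the second time point, a difference of 0.236 ± 0.541 points, higher in 9 of 13 pairs (exact two-sided sign-flip test, p = 0.139, adjusted p = 0.418 over 3 measures). The intermediate share changed by 0.106 ± 1.00 points (17.6% against 17.7%, higher in 7 of 13, p = 0.702, adjusted p = 0.870) and the neighbour difference by -0.0294 ± 0.615 (6.91 against 6.88 points, p and adjusted p = 0.870). The discordant share, added later, was 20.2% ± 4.64 and 20.5% ± 4.12 (difference 0.299 ± 0.824, higher in 8 of 13, p = 0.212, adjusted p = 0.424 over 4 measures). In 5 of the 13 pairs 1 library, 3 of the first and 2 of the second time point, had over 2% of its rows merged from both strands. Without these pairs, an alternative added after the data were seen, the differences were 0.279 points in mean methylation, 0.0894 in the intermediate share, -0.124 in the neighbour difference and 0.318 in the discordant share (8 pairs, exact test, adjusted p = 0.797, 0.953, 0.953 and 0.531). The same held within genomic contexts, added after the data were seen, where the smallest p was that of mean methylation in gene bodies (0.332 ± 0.610 points, higher in 9 of 13 pairs, p = 0.0649, adjusted p = 0.195 over 3 measures).

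**Figure D4:**
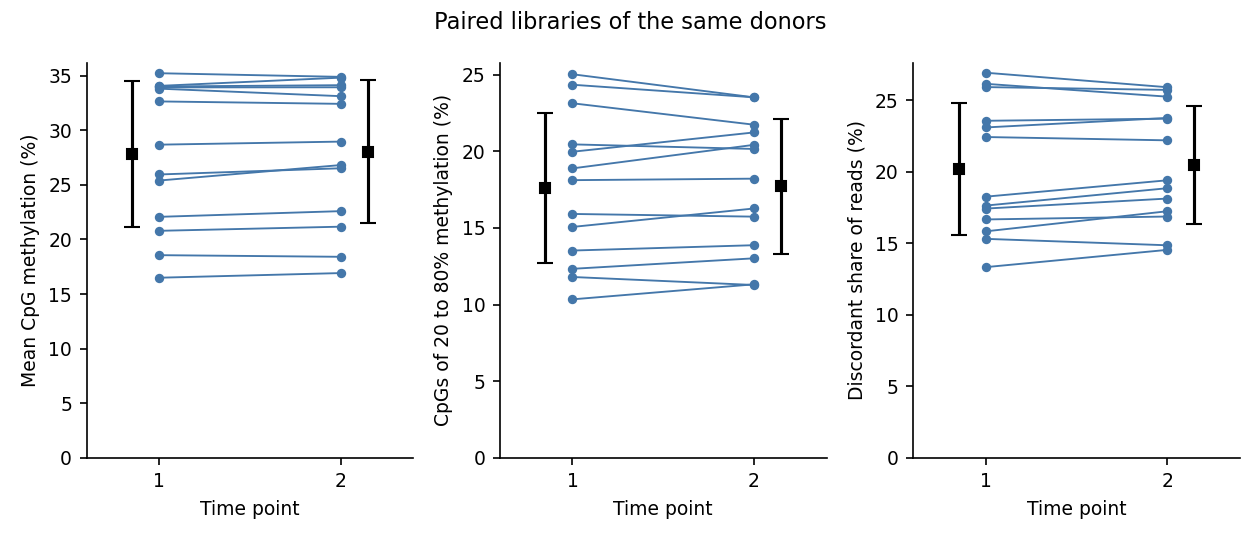
Mean CpG methylation, share of CpGs of 20 to 80% methylation and discordant share of reads, all in percent, at time point 1 and time point 2 of 13 donors (1 line per donor), with black squares and bars for the mean ± SD. The mean differences were 0.236, 0.106 and 0.299 percentage points.

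Single promoters that changed between time points were few. Of 6515 promoters tested with a quasi-binomial model with the donor as a block, 1 was called higher and 1 lower at the second time point (Benjamini-Hochberg adjusted over 6515 promoters at 0.05, two-sided), while 586 (8.99%) had an unadjusted p under 0.05. When the time points were exchanged at random within pairs, 16 of 100 splits, the real one included, gave at least 2 promoters, so chance cannot be excluded for these calls. AKAP7 (ENSG00000118507, chromosome 6, 131455607 to 131457607), an anchor of protein kinase A, went from 1.74% to 5.45% (difference 3.71 ± 7.21 points, higher in 7 and lower in 1 of 12 pairs, adjusted p = 0.0136 in the quasi-binomial model). GOT2 (ENSG00000125166, chromosome 16, 58767220 to 58769220), the mitochondrial aspartate aminotransferase, went from 8.38% to 1.81% (difference -6.56 ± 11.9 points, lower in 5 and higher in 1 of 11 pairs, adjusted p = 0.0097 in the quasi-binomial model). Limma on the paired differences called 0 promoters (2.10% with an unadjusted p under 0.05, adjusted p = 0.836 for both genes), and the model without the donor block called 0 (193 with an unadjusted p under 0.05). Leaving out 1 pair at a time gave between 0 and 4 promoters, and AKAP7 no longer passed in 3 and GOT2 in 1 of these 13 fits. The AKAP7 change lay between 1.91 and 4.06 points in these fits and that of GOT2 between -7.23 and -3.26. In the 8 pairs without a library of many merged strand rows 0 of 7364 promoters passed, with mean differences of 6.12 points at AKAP7 and -8.07 at GOT2 (adjusted p = 0.544 for both in the quasi-binomial model), and fewer pairs also have less power.

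The remaining promoters with the smallest p did not pass. Toward higher methylation they were PPP1R35, a centriole protein (1.87% to 3.20%, 13 pairs), NIPAL2 (0.0375% to 1.35%, 12 pairs), and ADGRL1, the adhesion receptor latrophilin (4.07% to 7.39%, higher in 9 and lower in 0 of 10 pairs), all with an adjusted p of 0.0921 in the quasi-binomial model. PKNOX2, a homeobox gene, came next (4.02% to 6.79%, 12 pairs, adjusted p = 0.105). Toward lower methylation they were KCNH8, a potassium channel (5.26% to 2.03%, lower in 9 and higher in 1 of 12 pairs), and RPP40, a subunit of ribonuclease P (10.6% to 5.42%, 10 pairs). CCDC122 and LACC1, which share a region and cannot be split, belonged to them too (3.16% to 0.0758%, lower in 7 and higher in 0 of 11 pairs). The adjusted p of each was 0.0921. Some of these changes rested much on 1 pair, without which they were 0.330 points at NIPAL2, 0.621 at PPP1R35, -2.80 at RPP40 and -1.75 at CCDC122 and LACC1. Of 9597 windows of 1000 bp, 1 passed and 745 (7.76%) had an unadjusted p under 0.05. It was chromosome 6 131456001 to 131457000, which holds the AKAP7 promoter CpGs and gave the same 1.74% and 5.45% (adjusted p = 0.0429 in the quasi-binomial model). Limma called 0 windows (262 with an unadjusted p under 0.05) and the model without the block 0 (284), and leaving out any 1 pair left 0 windows. The change of the AKAP7 window had the same range as that of the promoter, while up to 13116 windows were tested. Of 100 splits, 21 gave at least 1 window, and the 8 pairs without a library of many merged strand rows gave 0 of 12795.

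Other windows with a small p, none of which passed, lay toward higher methylation at NIPAL2 (chromosome 8, 99306001 to 99307000) and CDC42EP1, an effector of CDC42 (chromosome 22, 37957001 to 37958000, 4.46% to 8.42%). They also lay at ANKRD13B and CORO6 (chromosome 17, 27940001 to 27941000, 0.197% to 1.80%) and WNT5B, a WNT ligand (chromosome 12, 1640001 to 1641000, 0.524% to 2.07%). Toward lower methylation they lay at CHTOP (chromosome 1, 153606001 to 153607000, 38.6% to 22.2%, lower in 8 and higher in 0 of 10 pairs) and ADORA2A, an adenosine receptor (chromosome 22, 24819001 to 24820000, 12.6% to 8.55%). They lay also at KCNH8 (chromosome 3, 19189001 to 19190000, 5.41% to 1.97%), the CCDC122 and LACC1 region (chromosome 13, 44453001 to 44454000) and a window with no protein-coding gene (chromosome 4, 4868001 to 4869000, 29.04% to 23.95%). Their adjusted p was 0.299 or 0.302 in the quasi-binomial model. Without 1 pair the change was 0.346 points at WNT5B, 0.727 at ANKRD13B and CORO6 and 1.58 at CDC42EP1, and 0.330 and -1.75 at the NIPAL2 and the CCDC122 and LACC1 windows.

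No gene list changed as a whole. The smallest p of the 16 lists was that of imprinted promoters, 1.52 ± 2.46 points higher at the second time point (higher in 8 of 12 pairs, exact two-sided sign-flip test, p = 0.0576, adjusted p = 0.863 over 16 lists), and the adjusted p of the other lists was 0.863 or higher. In the discordant share, added after the data were seen, the smallest p were those of protocadherins (difference 4.17 ± 7.05 points, p = 0.0386) and T and NK cell markers (2.78 ± 4.36, p = 0.0547), both with an adjusted p of 0.438 over 16 lists in the exact test. Without the donor block the adjusted p was 0.997 for all 16 lists. Over all promoters tested 0 list members passed. Adjusted over the list alone, 1 of 12 HOX promoters was called higher and 1 lower, and 1 of 4 CLL surface marker promoters lower. HOXA5 went from 86.3% to 75.3% (lower in 9 of 10 pairs, adjusted over the list alone p = 0.0361 in the quasi-binomial model). HOXB9, named after its values were seen, went from 1.02% to 3.03% (higher in 4 and lower in 3 of 12 pairs). ROR1, a receptor kinase, went from 0.652% to 0.0993% (lower in 2 and higher in 1 of 13 pairs, adjusted over the list alone p = 0.0284 in the quasi-binomial model).

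The members with the largest differences in the other lists did not pass over the list alone. In the germline list DMRT1 had 15.6% at the first and 10.04% at the second time point and BOLL 18.6% and 22.03% (5 promoters tested). In the protocadherins PCDHA12 had 71.7% and 61.8% and PCDHA2 58.9% and 53.5% (9 tested). Among developmental transcription factors PAX6 had 18.6% and 25.7% and SOX14 24.9% and 31.7% (61 tested). Among imprinted genes H19 had 43.3% and 47.1% and CDKN1C 4.78% and 6.75% (11 tested). Among genes often studied in CLL SFRP1 had 31.4% and 32.98% and TWIST2 34.6% and 34.3% (6 tested), and among WNT inhibitors SOX17 had 28.6% and 24.6% and NOTUM 12.1% and 14.7% (10 tested). Tumour suppressors included CDKN2B at 3.56% and 0.943% (lower in 6 and higher in 4 of 12 pairs, adjusted over the list alone p = 0.0896 in the quasi-binomial model) and CDH1 at 12.99% and 17.03% (17 tested). Methylation enzymes included TET1 at 6.73% and 4.799% (15 tested) and housekeeping genes GPI at 12.6% and 9.66% (21 tested). T and NK cell markers included BCL11B at 12.1% and 17.2% (higher in 10 of 12 pairs, 6 tested) and myeloid markers CST3 at 15.2% and 10.9% (5 tested). B lineage genes included IRF4 at 0.443% and 0.0866% (11 tested), apoptosis genes BCL2 at 0.419% and 0.822% (9 tested) and CLL driver genes NOTCH1 at 0.530% and 0.697% (12 tested).

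Within single donors, the CpGs called different between the time points were few at these depths. Fisher's exact test between the libraries of a pair compares 2 libraries and not conditions. It called a median of 0.294% of the shared CpGs (range 0 to 3.41%, n = 13 pairs of 9221 to 381484 CpGs) at an adjusted p under 0.05 and a difference of at least 20 points. At CpGs with at least 20 reads the median was 0.636% and the highest 5.59% (1226 to 153894 CpGs). Over all pairs 9270 calls were higher and 9283 lower at the second time point, but single pairs leaned to one side. Of all calls, 50.4% came from 1 pair with 5272 higher and 4081 lower, and the other 12 pairs gave 3998 higher and 5202 lower. Pairs simulated without change, from the pooled level of each CpG, gave 0 calls in 13 pairs. Their median absolute difference per CpG was 3.93 points, against 6.02 in the real pairs. The simulation and Fisher's exact test hold counting error of independent reads only. These values therefore cannot part change over time from differences between separate libraries.

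On average, a donor's 2 time points resembled each other more than they resembled other donors. The second time point differed from its own first time point by 5.91 ± 0.935 points per CpG and from other donors' first time points by 8.19 ± 0.856, a difference of -2.28 (n = 13, one-sided permutation test, p = 1e-05, the smallest the permutations can give). The own partner was the closest library for 11 of 13 donors and the best correlated for 12 of 13. For 1 donor another donor's first time point was both closer (5.89 against 7.07 points) and better correlated (0.956 against 0.942), so a mixed-up sample is not excluded. That other donor's second time point had r = 0.971 with its own first time point and 0.945 with this donor's. With the first time points of further donors its r was at most 0.921. The libraries of these donors thus resembled each other in both directions, and both were counted as separate donors. The correlation across CpGs, which are not independent replicates, averaged 0.950 with the own partner and 0.898 with others.

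The 2 donors with a second library of the same sample give the difference between 2 libraries, 1 of each per donor and hence with no replicate check. The file names of the second libraries contain WGBS, and their labels do not state the kind. The second libraries listed 6501917 and 7178923 CpGs, far more than any RRBS library, with mean methylation over all their CpGs of 61.9% and 59.6%. At the 441340 and 444381 CpGs shared with the first library, the second was higher by 3.74 and 3.66 points, the mean absolute difference was 9.49 and 8.91 points and the correlation across CpGs 0.915 and 0.916. CpGs of intermediate methylation made up 22.8% and 23.96% in the first library but 11.5% and 11.9% in the second, while the discordant share was 26.5% and 24.9% in the first and 28.2% and 28.4% in the second. Fisher's exact test called 6.48% and 5.51% of the shared CpGs.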

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

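The mitochondrial calls, the tests of the CpG set and of read sampling, all tests of the spread at matched CpGs, the test of different CpGs for the named promoters, and the test of conversion were chosen only after the result was seen.

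Mitochondrial CpGs, which no comparison uses, held methylated calls above the limit that a count of 0 allows. Of 867505 calls, 1076 were methylated, a share of 0.124% (95% Wilson interval 0.117 to 0.132%), against a limit of 0.00035%. In 99 donors with at least 1000 such calls the median share was 0.0982% and 0 donors lay above 1%. The share was not correlated detectably with the discordant share at unmethylated CpGs (r = 0.0295, permutation p = 0.772, rho = 0.0601, p = 0.555, r = 0.0472 without the 2 farthest, n = 99). Unconverted cytosines, sequencing errors and methylated mitochondrial DNA all give such calls, and no test here parts them.

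Mean methylation and the discordant and intermediate shares of a library rose with the number of CpGs it listed. At the same CpGs as the 50 deeper libraries the correlation of CpG number with mean methylation was 0.0861, so a candidate explanation is that shallow libraries list more unmethylated CpGs. For the intermediate share read sampling alone is argued against, because with every CpG thinned to 10 reads its correlation was still 0.716, while thinning cannot move the other 2 measures by its construction. At CpGs with at least 20 reads the correlation was 0.192 for the intermediate share and 0.271 for mean methylation. That of the discordant share stayed well above both, as given in the Results. What the choice of deep CpGs does was not tested. The intermediate share kept a correlation of 0.287 at the same CpGs, but of 0.0213 and 0.0977 within the libraries with fewer and with more CpGs, and this stays open.

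The donor spread of the 10 named promoters had more than 1 source. The SD at matched CpGs was a median 0.234 of the SD, under 0.5 for 7 promoters and over 0.8 for GRAMD4, CDKL4 and PRR33, so different CpGs in different libraries may account for most of the spread at the 7. Whether a variant at a single CpG adds to it cannot be told apart, since the correlation between CpGs of a promoter had a median of 0.446, between the limits set for the test. Noise of single libraries may account for what is left at shared CpGs over the 8 promoters with enough pairs, where the median difference within donors was 0.949 of that between donors (6.23 against 6.56 points, with a median SD of 31.95 over all listed CpGs), but not at GRAMD4 (9.14 against 41.7) and less so at PRR33 (14.7 against 31.9), where the spread stayed at matched CpGs. For the 10 promoters chosen at matched CpGs the correlation between CpGs was 0.775 (range 0.588 to 0.937). They were chosen for a large SD of the promoter mean, which needs CpGs that vary together. The correlation was thus largely set by that choice and cannot test a single-CpG variant. For the 8 with enough pairs the median difference within donors was 0.258 of that between donors (8.37 against 32.4 points, but 14.3 against 19.4 at CDKL4). Over the set this argues against library noise. A DNA variant that sets a whole fragment and a state fixed in each leukemic clone stay open.

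Intermediate CpGs of imprinted promoters had fewer discordant reads than those of other promoters. At matched local CpG density the difference was -29.4 points, and leaving out any 1 imprinted gene it stayed at -25.4 or lower, nearest to 0 without MEST. The density and single-gene tests argue against these explanations. The mitochondrial share of methylated calls was low, 0.124%, but it rested on 5 CpGs per library. Conversion is also common to imprinted and other promoters of a library, so this share cannot test poor conversion as the source of a difference between them. Methylation of 1 parental copy along whole reads is a candidate explanation, which was not tested with parental alleles.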

How the results depend on the processing

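The comparison at the same CpGs as the 50 deeper libraries, those without libraries or pairs of many merged strand rows, the SD at matched CpGs, the common panel for contexts and 20 reads for imprinted promoters were chosen only after the data were seen. Of 1125 values under alternatives, 975 kept their direction and side of the threshold, 52 changed direction, 64 lost a call or part of a count of calls and 7 gained one, and 27 values without a test moved by more than their spread. The 5-read minimum was not run, because no listed CpG has fewer than 11 reads. Where a value changed, the cause was not tested unless given.

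With 10 to 90% as intermediate, by its construction, the intermediate share was 27.9%, the methylated share 13.6%, and the discordant share 51.9%, 6.30% and 29.1% at intermediate, unmethylated and methylated CpGs. With 20 reads the neighbour difference was 6.23 points and the discordant share 50.8% at intermediate and 29.7% at methylated CpGs. First time points minus single-time donors changed to 0.783 (panel), 0.807 (same CpGs) and 1.58 (without the 3 libraries) in mean methylation, to -2.91 (100000 CpGs) and 0.137 (same CpGs) in the intermediate share, to -0.226 (20 reads), -0.0963 (thinned) and -0.329 (100000 CpGs) in the neighbour difference, and to -2.16 (100000 CpGs), 0.329 (same CpGs) and 0.380 (without the 3 libraries) in the discordant share. Gene bodies minus intergenic DNA became -2.58 at 20 reads. The correlation of CpG number became 0.0861 with mean methylation and 0.0432 with the discordant share at the same CpGs, and 0.192 with the intermediate share at 20 reads.

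Over time, the intermediate share changed by -0.116 at 20 reads and the neighbour difference by 0.0611 (20 reads) and 0.0521 (thinned). Without the donor block (pairing) 0 promoters and 0 windows passed (193 and 284 with an unadjusted p under 0.05). Limma called 0 and 0, and the 8 pairs of few merged strand rows gave 0 and 0. The block changed no call of the global levels or of whole lists. With 10 calls the CLL driver list changed by 1.8e-05 and the genes often studied in CLL by -0.328. Leaving out 1 pair at a time, the change ranged from 0.138 to 0.313 for mean methylation, from -0.0126 to 0.241 for the intermediate share, from -0.104 to 0.0853 for the neighbour difference and from 0.207 to 0.409 for the discordant share. It ranged from -0.0330 to 0.107 for B lineage genes, from -0.0111 to 0.0252 for CLL drivers, from -0.417 to 0.0577 for germline genes, from -0.687 to 0.0397 for HOX genes, from -1.64 to 0.0640 for protocadherins and from -0.403 to 0.319 for WNT inhibitors. Promoters past the threshold ranged from 0 to 4, and windows from 0 to 0, where the AKAP7 window lost its call each time and kept a change of 1.91 to 4.06 points.

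With 50 calls per donor the list mean was 0.272% for apoptosis and 0.716% for B lineage genes. With 500 bp it was 0.258% and 0.667%, and 2.32% for housekeeping genes and 1.17% for methylation enzymes. Differences from random lists that changed direction, none of them past the threshold, were in the discordant share at 500 bp apoptosis 0.0413, surface markers 0.289, myeloid -1.04, T and NK -3.71 and tumour suppressors 0.235 (0.0101 at 50 calls). In the SD they were at 500 bp apoptosis 0.0370, surface markers 0.138, methylation enzymes 0.0882, myeloid -0.114 and WNT inhibitors 0.542, and at 50 calls housekeeping -0.0201, methylation enzymes 0.0109 and myeloid -0.615. In the SD at matched CpGs they were at 500 bp germline -2.61, surface markers 0.218 and tumour suppressors 0.0797, and at 50 calls surface markers 0.0850 and housekeeping -0.0645. Second libraries at 20 reads were higher by 2.73 and 2.48 points, with absolute differences of 8.04 and 7.07 and correlations of 0.931 and 0.932.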

Other observations

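The gene families, the splits of the time points and the values of second libraries were chosen only after the data were seen, and the drift test was written before its result.

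Promoters were also counted by gene families named by symbol. Of 12005 promoters, 1399 (11.7%) had a mean methylation of 20% or more. Zinc finger genes of the ZNF name reached it at 51 of 356 promoters (14.3%), solute carriers (SLC) at 37 of 226 (16.4%), FAM genes at 22 of 114 (19.3%) and G protein-coupled receptors of the GPR name at 9 of 30. The counts were low in ribosomal protein genes, with 0 of 32 RPS promoters and 1 of 32 RPL promoters, in ZBTB genes with 1 of 34, ubiquitin-conjugating UBE genes with 1 of 32 and PPP phosphatase genes with 2 of 58. Other families lay nearer the overall share, such as CCDC at 11.5%, WDR at 12.2% and TMEM at 10.6%. These values were not tested.

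The spread of second libraries from first ones was lopsided. Fisher's exact test called 21470 CpGs higher and 7118 lower in the second library of 1 sample and 18545 and 5929 in that of the other. The discordant share over all CpGs of the second libraries was 34.04% and 38.1%.

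Chance cannot be excluded for the regions called between time points. When the time points were exchanged within pairs at random, 16 of 100 splits, the real one included, gave at least the 2 promoters of the real split, and the highest other split gave 7. For windows, 21 of 100 splits gave at least 1, and the highest other split gave 8. The share of promoters with an unadjusted p under 0.05 was 8.99% in the real split and a median of 9.36% in the others. The AKAP7 and GOT2 changes are therefore hypotheses that need other samples.

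Promoters with many discordant reads may drift more over time. Across 415 promoters of 20 to 80% mean methylation, Spearman's rho of the discordant share with the SD of the change over pairs was 0.190, and the partial rho given depth and the binomial spread at the mean methylation was 0.160, between the limits of 0.1 and 0.2 set before. The test was written for the size of the change and was run on its SD over pairs. It leaves the hypothesis open.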
